A study of Mus musculus with 2 samples.

How the data were processed

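Chromatin from facial prominences of day 10.5 embryos was immunoprecipitated with an antibody against H3K4me1 and sequenced, with fragments of 300 to 500 bp per the labels. The labels define 1 group with 2 biological replicates, pools of 69 and 51 embryos of both sexes. The labels mention possible controls, which were not analysed here.

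The authors deposited 4 peak lists in narrowPeak format on mm10: 1 per replicate, 1 pooled list and 1 replicated list. Per the text files deposited with them, the list of replicate 1 was derived from its alignment and 2 further files and that of replicate 2 from its alignment and 1 further file, the pooled list from both alignments, and the replicated list from the pooled list and the lists of both replicates. The aligner, the peak caller, its threshold and the rule that makes a peak replicated are not given in the sources used here. Each peak carries the fold enrichment, a ratio, and the -log10 p and -log10 q given by the authors. The smallest -log10 p was about 2 in every list, so the lists hold weak peaks as well as strong ones. These values belong to the peak and its list, and were used only to describe, rank or filter peaks. The number of reads is not known, and differences in peak number between replicates can follow from depth, from the further files or from the tissue.

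Sequence and annotation were GRCm38.p6, the assembly known as mm10, with GENCODE M21. No peak ran past the end of a chromosome and none lay mostly in gaps of that sequence. Chromosomes 1 to 19, X and Y were used, which left out 3 peaks of replicate 1, 1 of replicate 2, 2 of the pooled and 1 of the replicated list. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

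Overlapping peaks of a list were merged before covered length was computed. Overlap between replicates and genomic location were compared with 100 random placements of the peaks on the same chromosome, in gap-free sequence. Sequence to which reads cannot be mapped uniquely was not left out of the placements, which can make the excess over random placement too large. A peak was distal when no protein-coding start site lay within 2 kb. For each of 21728 protein-coding genes on the autosomes and X, the length covered by peaks within 50 kb either side of the start site was summed. A gene list was tested by its median covered length against 10000 random lists of the same size, drawn within deciles of local gene density (start sites within 100 kb), with a two-sided permutation p, Benjamini-Hochberg adjustment over 19 lists and a threshold of 0.05. Replicate differences were log2 ratios of covered length plus 1000 bp, replicate 2 over replicate 1. Motifs on either strand were counted in 20000 randomly drawn distal replicated peaks, of which 18966 had a control region of the same chromosome and length (found within 200 random tries), GC content within 2 percentage points, and no overlap with pooled peaks or start sites. The interval of the ratio came from 1000 bootstrap resamples.

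Gene lists, motifs, tests, most alternatives and the rule for named genes were chosen before the data were examined. The rule named the 3 most and the 1 least covered gene of each list, the 15 most covered genes overall (1 per 200 kb), the nearest gene to the 15 strongest and 5 widest replicated peaks, the 10 largest replicate differences, and any cranial mesenchyme transcription factor. Genes that contain a strong peak are named as well, since the nearest start site can belong to a neighbour. The orders of motif letters, the match on repeat-masked sequence, a limit of 300 tries per control region and 4 further settings of the list test were added after seeing the data.

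The overlap, list and motif computations were tested on simulated data, and those of start sites and of the closing section were not. A planted overlap of 60.9% between lists was measured as 61.6%. The following simulations of the list test counted unadjusted p-values, so the adjusted test would call at most as many lists. With real covered lengths exchanged between genes, the list test on 21728 genes called 30% of lists raised 1.5-fold, 62% raised 2-fold and 95% raised 3-fold. With the replicated peaks shifted along the chromosomes, so that no list had an effect, 1% to 9% of runs called a given list, except 30% for Hox genes, which lie at 4 loci, and 69% for olfactory receptors, which lie at 170 loci. For these clustered lists the p-value is too small, and a setting with 1 gene per 200 kb was run for every list, without a simulation of its own. A TEAD site planted in simulated regions was recovered with a ratio of 1.95, and 1 of 17 other motifs had an interval that left out 1. Alternatives covered the peak threshold, the definition of overlap, the distance that counts as distal, the window around genes, the background of random lists, the peak list used and each replicate left out.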

Results

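H3K4me1, the histone mark of enhancers and of the sequence flanking promoters, was mapped by chromatin immunoprecipitation and sequencing in the facial prominences of mouse embryos at embryonic day 10.5. At this stage the tissue that will form the face consists of neural crest mesenchyme covered by ectoderm, with smaller contributions from other lineages. The study held 1 group with 2 biological replicates of strain B6NCrl, each a pool of male and female embryos. Replicate 1 pooled 69 embryos and replicate 2 pooled 51. With a single tissue and a single mark, the comparisons were those of the replicates with each other, of the peaks with their genomic surroundings, and of gene groups with other genes. Values per replicate are given as mean ± SD with n = 2. All coordinates are those of mm10. Read depth was not given in the sources used here, so no interval that depends on it was computed.

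The peak lists of the replicates covered a similar portion of the genome, as many short intervals. Replicate 1 had 265834 peaks that covered 150 Mb, and replicate 2 had 217686 peaks that covered 122 Mb (136 ± 19.9 Mb, SD, n = 2), so the first list held 1.22 times as many peaks. These regions made up 5.67% and 4.61% of the gap-free genome. Median peak width was 335 bp in replicate 1 and 348 bp in replicate 2. Among peaks with a -log10 q of at least 5 it was 733 bp and 816 bp, so width depended on the threshold. The authors' pooled list held 255974 peaks, and their replicated list held 167628 peaks with a median width of 636 bp that together covered 155 Mb. Every replicated peak was identical to a pooled peak.

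The regions marked in one pool of embryos were largely marked in the other. Of the peak length of replicate 1, 64.6% was also covered in replicate 2, against 5.10% with randomly placed peaks, a 12.7-fold excess. Of the peak length of replicate 2, 79.5% was covered in replicate 1, against 6.23% at random, a 12.8-fold excess. Overlap followed peak strength. In the top quartile of peaks by fold enrichment, 96.6% of replicate 1 peaks and 99.1% of replicate 2 peaks met a peak of the other replicate, while in the lowest quartile the shares were 35.7% and 64.6%. Over 138930 replicated regions with a peak in both replicates, Spearman's rho of fold enrichment was 0.64. This correlation is across regions, which are not independent replicates. The share of pooled peaks kept in the replicated list was 65.5% (exact binomial 95% interval 65.3 to 65.7%, counting error only), and it was 19.5% in the lowest quartile of fold enrichment and 99.98% in the highest. In the replicated list, 12.3% of the peaks met a peak of replicate 1 alone, 3.95% a peak of replicate 2 alone and 0.83% a peak of neither.

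The mark lay mostly away from promoters. Of the replicated peaks, 81.2% were distal, that is, over 2 kb from every annotated protein-coding start site (82.6 ± 1.58% in the replicates' own lists, SD, n = 2). Introns held 41.3% of the peaks, intergenic sequence 37.1% and exons 2.82%. Promoters were still the most enriched class, with 18.8% of the peaks against 5.93% of the same peaks placed at random, a 3.18-fold excess. Introns were 1.17-fold and exons 1.26-fold above random placement, and intergenic sequence was at 0.66 of it. Each of these observed shares lay outside the range of all 100 random placements. Promoter peaks were wider (median 882 bp against 592 bp) and had higher fold enrichment (median 3.89 against 3.15) than distal ones.

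Around start sites, taken as 1 per gene, H3K4me1 coverage formed a double peak with a dip at the start site itself. In the direction of transcription, 29.2 ± 0.41% of bases were covered between 500 and 250 bp upstream, 24.8 ± 1.06% in the first 250 bp downstream, and 38.9 ± 1.69% between 750 and 1000 bp downstream (SD, n = 2 throughout). The difference between the dip and the downstream maximum was larger than the spread between replicates, and both replicates showed the same order. Summits were placed by the nearest of all annotated protein-coding start sites, and their density showed no such dip. They were 4.28 ± 0.56 times as dense within 250 bp of a start site as in the genome as a whole. The ratio was 4.20 ± 0.575 at 250 to 500 bp, 4.24 ± 0.38 at 500 to 1000 bp and 1.15 ± 0.003 at 5 to 10 kb. Of 21911 protein-coding genes, 69.1% had a replicated peak within 2 kb of the start site, and 29.2% had the start site inside one.

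**Figure D1:**
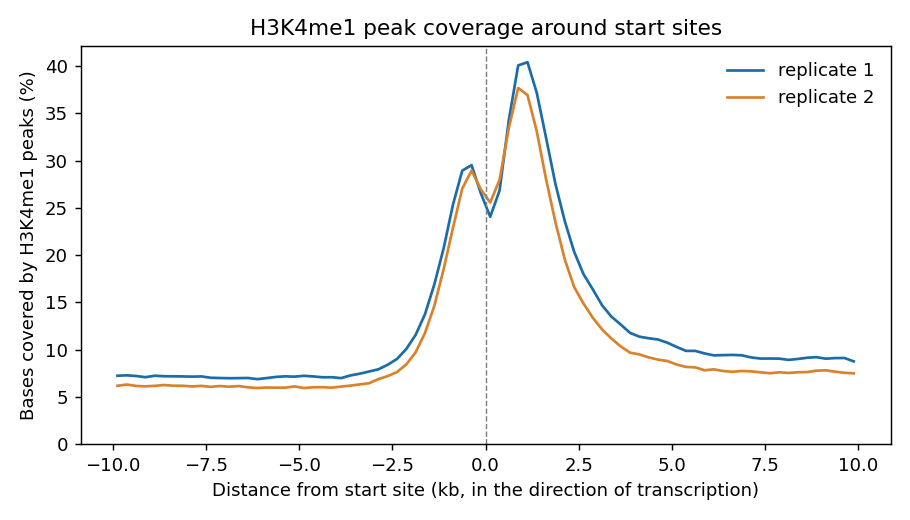
Share of bases covered by H3K4me1 peaks (percent, vertical axis) in 250 bp bins from 10 kb upstream to 10 kb downstream of protein-coding start sites (kb, horizontal axis), with 1 line per replicate. Both lines dip at the start site and reach their maximum about 1 kb downstream, at 40.4% in replicate 1 and 37.7% in replicate 2.

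Genes of the facial mesenchyme and of facial signalling stood in the most densely marked surroundings of the 19 gene lists. The 40 transcription factors of the cranial mesenchyme had a median of 25.4 kb of replicated peaks within 50 kb of their start sites, 5.11 times the 4.96 kb of random lists (22.8 ± 3.51 kb in the replicates' own lists, SD, n = 2). The 29 genes of facial signalling had a median of 23.6 kb, 4.72 times random (20.2 ± 3.72 kb, SD, n = 2), and the 22 genes of facial ectoderm had 17.6 kb, 2.69 times random (15.1 ± 1.29 kb, SD, n = 2). With random lists matched on promoter CpG content in place of gene density, the ratios were lower, at 2.99 for cranial mesenchyme, 2.79 for facial signalling and 2.09 for facial ectoderm. Lists of other tissues then had ratios above that of facial ectoderm, without passing the test described below. These were erythroid and myeloid (2.83), photoreceptor (2.49), cardiac (2.42) and spermatid genes (2.21). The erythroid and myeloid ratio was also above that of facial signalling. With a single tissue, whether the mark around the facial lists is particular to the face could not be tested. Olfactory receptor genes, which are used by mature sensory neurons, had a median of 0 kb, and 881 of 1092 had no peak within 50 kb. The median over all 21728 genes tested was 6.66 kb.

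In the two-sided permutation test with 10000 random lists matched on local gene density, the Benjamini-Hochberg adjusted p over the 19 lists was 0.00127 for cranial mesenchyme, facial signalling and olfactory receptors and 0.0038 for facial ectoderm. The smallest unadjusted p that this number of lists can give is 0.0002. Cranial mesenchyme, facial signalling and facial ectoderm also passed in the list of each replicate alone. The p-values describe these libraries, since genes are not replicates. For olfactory receptors the call ended when the random lists were matched on promoter CpG content, because those lists also had a median of 0 kb (adjusted permutation p = 1), and a simulation without any effect called this clustered family in 69% of runs. The CpG-matched lists were drawn from all genes, the receptors included, so that comparison was in part one of the family with itself. It cannot decide whether promoter CpG content accounts for the call. The call held with 1 gene per 200 kb (0 bp against 8205.5 bp, adjusted permutation p = 0.00127) and with lists matched on density and CpG together (0 bp against 581 bp, adjusted permutation p = 0.00855). The simulation counted unadjusted p-values and was not repeated for these settings, so their p-values may be too small as well.

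Among the mesenchyme regulators, 37 of 40 lay above the median of all genes and 22 lay in the top 10%. The 40 genes make up 37 loci at 1 gene per 200 kb, so windows of neighbouring members can hold the same peaks. Per-gene lengths from here on are means of the replicates' own lists. Prrx2, a paired-type homeobox gene of craniofacial and limb mesenchyme, had 52.7 ± 1.28 kb, and Alx4, a homeobox gene of the frontonasal region, had 50.1 ± 10.4 kb (SD, n = 2). The Dlx genes, which pattern the pharyngeal arches from proximal to distal, had 44.7 ± 1.64 kb at Dlx3, 39.3 ± 0.35 kb at Dlx1, 39.1 ± 0.33 kb at Dlx4 and 35.9 ± 0.23 kb at Dlx2 (SD, n = 2). Dlx5 and Dlx6 had less, with 14.6 ± 0.02 kb and 15.8 ± 0.26 kb. High values were also found at Nr2f2 (35.1 ± 2.20 kb), Foxf1 (33.5 ± 1.16 kb), Pax7 (32.4 ± 6.47 kb), Twist2 (31.0 ± 4.12 kb), the AP-2 gene Tfap2a (26.4 ± 1.10 kb) and Pax3 (26.0 ± 4.33 kb). Sox9 and Sox10, regulators of cartilage and of neural crest derivatives, had 24.9 ± 1.44 kb and 24.3 ± 1.70 kb. The members with little mark were Alx1 (4.28 ± 1.19 kb), Snai2 (3.26 ± 1.71 kb) and the cleft palate gene Tbx22 on the X chromosome, which had no peak in either replicate.

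**Figure D2:**
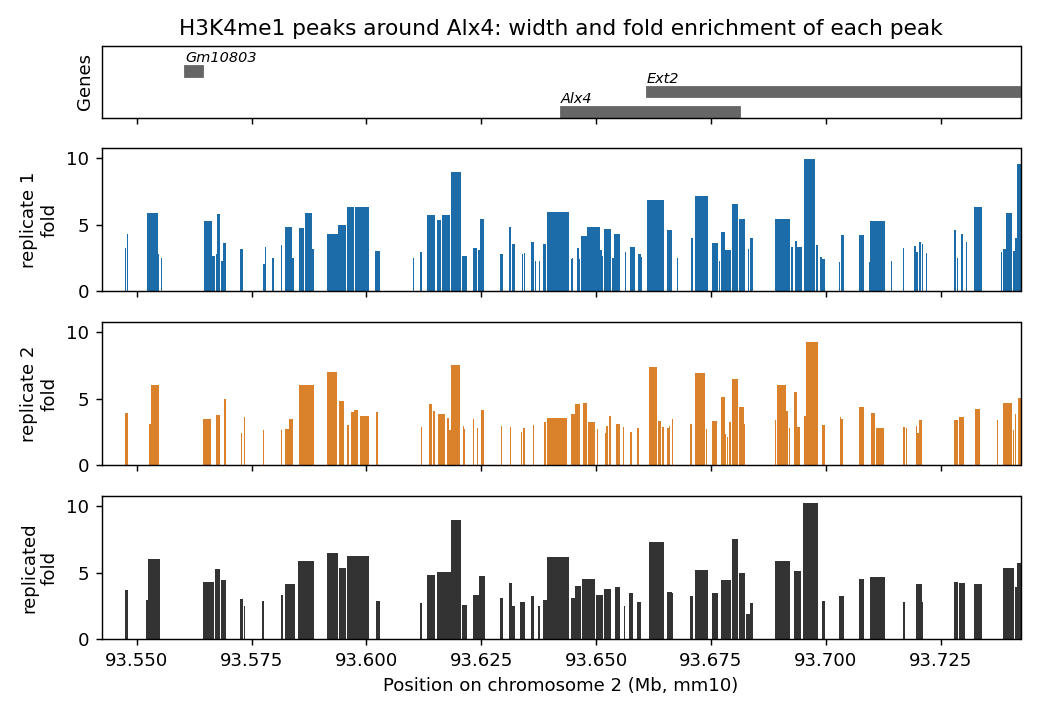
H3K4me1 peaks in the 200 kb of chromosome 2 (Mb, horizontal axis) centred on the start site of Alx4, with gene bodies on top and, below, each peak of replicate 1, replicate 2 and the replicated list drawn to its width and to the authors' fold enrichment (vertical axes). Replicate 1 had 111 peaks here, replicate 2 had 97 and the replicated list 69, and the peaks run through Alx4 and the neighbouring Ext2.

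All 29 facial signalling genes lay above the median of all genes in the replicated list, and 11 lay in the top 10%. The highest were Rara, a retinoic acid receptor (55.8 ± 2.26 kb), Notch2 (49.9 ± 1.88 kb) and the Hedgehog receptor gene Ptch1 (36.4 ± 2.20 kb), and the lowest was the Wnt antagonist gene Dkk1 (6.50 ± 1.36 kb, SD, n = 2 throughout). Dkk1 had 6.80 kb of replicated peaks, just above the median of 6.66 kb over all genes. In the ectoderm list, 17 of 22 genes lay above that median, led by the epithelial transcription factor gene Grhl3 (28.8 ± 3.79 kb), the Notch ligand gene Jag2 (26.1 ± 2.55 kb) and the tight junction gene Cldn7 (24.0 ± 2.96 kb). Krt5, a keratin gene of stratified epithelium, was lowest with 2.30 ± 1.07 kb.

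The remaining 15 lists did not pass the test, 11 of them with a ratio above 1 and 4 below it. Forebrain and eye progenitors were at 2.24 times random and cartilage and bone at 2.10 times, both with an adjusted permutation p of 0.083. Cranial neurons and placodes followed at 1.97 times (adjusted permutation p = 0.124), head mesoderm and muscle at 1.74, pharyngeal endoderm at 1.74, endothelium at 1.69, housekeeping genes at 1.68, cardiac genes at 1.63, limb and trunk factors at 1.56, photoreceptor genes at 1.55 and spermatid genes at 1.29. Some of these fell below 1 elsewhere: cardiac (0.97) and spermatid genes (0.60) within 20 kb, and limb and trunk factors (0.96) within 100 kb. With lists matched on promoter CpG, limb and trunk factors (0.99) and pharyngeal endoderm (0.96) did so. In the main test, lymphoid genes were at 0.91, Hox clusters at 0.86, erythroid and myeloid genes at 0.83 and liver and gut genes at 0.57. The direction of 3 of these 4 low ratios depended on the background, while liver and gut genes stayed below 1 in every setting. With lists matched on promoter CpG content in place of density, lymphoid genes were at 1.79, Hox clusters at 1.25 and erythroid and myeloid genes at 2.83, and with lists matched on both, lymphoid genes were at 1.91, erythroid and myeloid genes at 1.86, liver and gut genes at 0.78 and Hox clusters at 0.65, further below 1 than in the main test (adjusted permutation p = 0.065). In a window of 20 kb, head mesoderm and muscle (3.15 times random), forebrain and eye progenitors (2.93) and cranial neurons and placodes (2.54) passed, with adjusted permutation p of 0.00456, 0.00633 and 0.00977. Within 50 kb, their ratios were 1.30, 1.23 and 1.28 when the lists were matched on promoter CpG content in place of density, and 1.72, 1.78 and 1.67 when matched on both. In these 50 kb settings, cardiac genes rose to 2.42 and 2.97, photoreceptor genes to 2.49 and 2.29 and spermatid genes to 2.21 and 1.74, without passing. Single members of these lists still had long covered stretches, such as the cartilage collagen gene Col2a1 (28.7 ± 0.90 kb), the osteoblast factor gene Sp7 (27.7 ± 0.58 kb), the endothelial factor gene Fli1 (44.9 ± 6.57 kb), the head muscle regulators Ebf3 (39.8 ± 3.08 kb) and Tbx1 (33.0 ± 2.53 kb), Eya2 of the placodes (36.5 ± 4.24 kb) and Lmx1b (44.0 ± 3.96 kb). Such stretches were also found at genes of blood and liver, with 28.8 ± 1.12 kb at Cd4, 26.6 ± 3.04 kb at Nfe2, 23.0 ± 1.70 kb at Apoa2 and 21.1 ± 2.30 kb at Cd79a (SD, n = 2), while the liver gene Serpina1a and the B cell gene Ms4a1 had no peak within 50 kb in either replicate. In simulations on the same 21728 genes, 95% of lists raised 3-fold and 62% of lists raised 2-fold were called by their unadjusted permutation p. The main test used adjusted p-values and would call at most as many. A difference of the size seen in these 15 lists could therefore be missed. The 50 kb windows also take in neighbouring genes: the rod photoreceptor gene Gnat1 had 49.5 ± 1.57 kb but only 0.52 kb of replicated peaks within 2 kb of its start site.

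**Figure D3:**
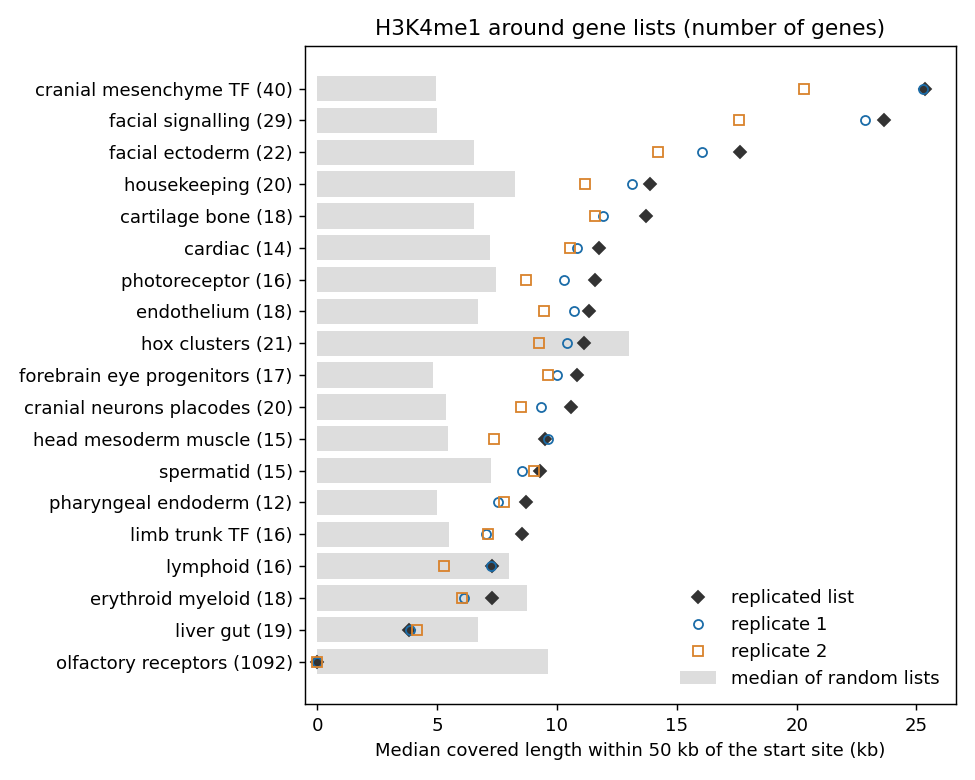
Median length covered by H3K4me1 peaks within 50 kb of the start site (kb, horizontal axis) for each gene list (vertical axis, number of genes in brackets). Diamonds show the replicated list, circles replicate 1, squares replicate 2 and grey bars the median of random lists; cranial mesenchyme transcription factors lie highest, at 25.4 kb against 4.96 kb.

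Over all genes tested, the 15 with the most H3K4me1 around them, counted once per 200 kb, were of varied function. Among them were Mrpl23 (62.6 ± 5.52 kb), Ccdc85c (61.4 ± 0.38 kb), Bahcc1 (61.3 ± 1.70 kb), Ahdc1 (61.2 ± 3.42 kb), the TGF-beta mediator gene Smad3 (56.9 ± 3.81 kb), Gse1 (56.5 ± 4.22 kb), the nuclear receptor corepressor gene Ncor2 (55.9 ± 5.41 kb), the forkhead gene Foxp4 (55.6 ± 2.39 kb), Tns4 (55.1 ± 3.89 kb), Flrt1 (54.2 ± 4.86 kb) and Ngfr, a neurotrophin receptor gene expressed in neural crest (54.2 ± 3.29 kb, SD, n = 2 throughout). Asb6, also in this group with 55.5 ± 1.49 kb, is a neighbour of Prrx2 on chromosome 2. The 95th percentile over all genes was 30.9 kb of replicated peaks.

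The strongest single peak lay within Ncor2 on chromosome 5 (125156497 to 125161731), with a fold enrichment of 16.6 in the pooled calling, 15.5 in replicate 1 and 15.3 in replicate 2. Peaks within Rara on chromosome 11 (98958763 to 98971243, fold enrichment 14.6), Cmip on chromosome 8 (117331821 to 117336282, 14.4) and Zfp423 on chromosome 8 (87828297 to 87839244, 14.3) came next among separate loci. Other top peaks lay in Msi1, Chd3, Spsb4, Foxp4, Glis2 and Ptp4a3, and within 10.7 kb of the start site of Ski, a repressor of TGF-beta signals. The widest peak spanned 26256 bp in Gse1 on chromosome 8 (120541469 to 120567724), and 98.0% of it was covered in replicate 1 and 96.2% in replicate 2. Further wide peaks lay at the start of Smad3 (23707 bp), within Sept9 (21667 bp) and at Cxxc5 (21431 bp).

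Replicate 2 had less covered length than replicate 1 around 73.2% of all genes, with a median log2 ratio of -0.16 (on covered length plus 1000 bp). Relative to that median, list medians ranged from -0.13 for facial signalling to 0.16 for olfactory receptors and for liver and gut genes. Hox genes were at 0.12 and cranial mesenchyme at 0.02. Before that subtraction, the olfactory receptor and liver and gut medians were both 0.0, the value that genes without peaks in either replicate take. The olfactory receptors had a median of 0 kb in both replicates, so their 0.16 does not show more mark in replicate 2. Among mesenchyme regulators, 34 of 40 had less length in replicate 2, although their median log2 ratio of -0.14 was close to that of all genes. The share of 73.2% also counts genes without peaks, which cannot be lower. Single log2 ratios were -0.84 at Snai2, -0.69 at Alx3, -0.55 at Lhx8, -0.42 at Alx4 and -0.40 at Pax7, while Hand2, a regulator of the mandibular arch, was at 0.26. The 10 largest differences of all, such as Tmem14a (-1.45), Larp4b (-1.39) and the proteoglycan gene Lum (-1.28), were at genes with at most 6.17 kb covered in replicate 1, and all were lower in replicate 2. These comparisons set 1 library against 1, so none of them could be tested.

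The mark was sparse on the X chromosome. The replicated list had 8.07 peaks per Mb there, while the autosomes ranged from 54.0 per Mb on chromosome 14 to 102 per Mb on chromosome 11, with a median of 67.4. Per protein-coding gene, the X chromosome had 1.39 replicated peaks and the autosomes 4.94 to 11.7. Both replicates showed this, with 13.6 peaks per Mb on X in replicate 1 (autosomal range 86.5 to 159) and 11.4 in replicate 2 (69.8 to 133). Genes on X were the least covered members of 5 of the 19 lists, namely Tbx22, Sox3, Cdx4, Opn1mw and the housekeeping gene Hprt, which had 0.91 ± 0.44 kb (SD, n = 2). No peak of any list lay on the Y chromosome, although the pools held male embryos. Whether reads or peaks on Y were left out in the processing is not given in the sources used here. Their absence can therefore not be read as absence of the mark.

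**Figure D4:**
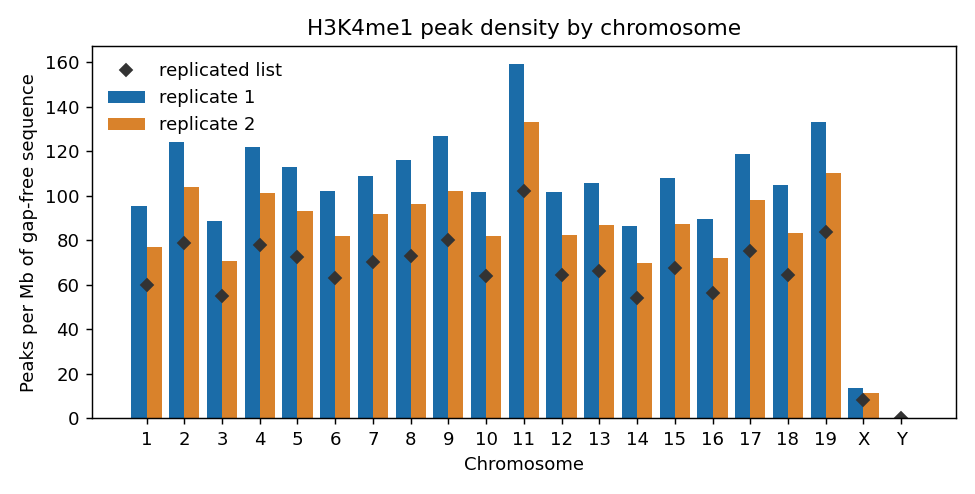
H3K4me1 peaks per Mb of gap-free sequence (vertical axis) on each chromosome (horizontal axis), with bars for the replicates and diamonds for the replicated list. The X chromosome, at 8.07 replicated peaks per Mb, lies below all autosomes, and the Y chromosome has none.

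Distal peaks carried the binding motifs of homeodomain proteins more often than control regions did. The core site TAATTA, bound by many homeodomain proteins including those of the Alx, Dlx, Msx and Prrx families, was present in 18.1% of 18966 distal replicated peaks and in 11.9% of controls matched on chromosome, length and GC content, a ratio of 1.52 (95% bootstrap interval 1.46 to 1.59). A TWIST-type E-box (CAGATG) within 10 bp of TAATTA was present in 0.496% of peaks and 0.185% of controls, a ratio of 2.69 (1.88 to 4.20), which was 7.0 (3.95 to 15.2) in replicate 1's own list, where 0.057% of controls had it. It was lower, at 2.0 (1.38 to 2.96), when the controls were also matched on repeat-masked sequence, and 2.35 (1.51 to 3.83) in 500 bp around summits. Part of the ratio of 2.69 came from both motifs being in the same region more often, in 2167 peaks and 1359 controls, of which 4.34% and 2.58% had them within 10 bp. Ratios were also above 1 for a nuclear receptor direct repeat (3.22, 2.18 to 5.30), MEF2 (1.70, 1.42 to 2.08), EBF (1.68, 1.48 to 1.91), TEAD (1.30, 1.24 to 1.37), FOX (1.27, 1.20 to 1.35) and AP-2 sites (1.27, 1.22 to 1.32). Smaller ratios were found for TCF/LEF (1.16), MEIS (1.12), GATA (1.09), SOX (1.07) and TWIST-type E-boxes alone (1.07), each with an interval above 1. NFI sites were rare, in 0.142% of peaks and 0.032% of controls (ratio 4.5, 2.1 to 15.5), and the ratio depended on which controls were drawn: it was 2.07 (1.17 to 4.43) in a second draw with more tries per region, where the direct repeat was at 2.37 (1.67 to 3.47). In the replicates' own lists the NFI ratio was 13.0 (3.2 to 38.0) in replicate 1 and 1.43 (0.5 to 4.67, which includes 1) in replicate 2.

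Sites of CTCF (1.27, 0.98 to 1.63) and ETS factors (0.88, 0.59 to 1.32) could not be told from 1, although CTCF was at 1.75 (1.33 to 2.30) in 500 bp around summits. The direction of ETS turned in replicate 2's own list, at 1.73 (1.10 to 2.94). It also turned, with intervals that included 1, in replicate 1's own list (1.58) and around summits (1.29). HNF1 sites of liver and gut were present in 0.005% of peaks and of controls. The AP-1 ratio of 1.09 (1.03 to 1.14) was 0.98 when the controls were also matched on repeat-masked sequence. Intervals were above 1 for 15 of the 18 motifs, so sequences with the same letters in another order were counted too: the homeodomain, MEF2 and EBF sites had a ratio above that of every such sequence (at most 1.17, 1.36 and 1.48), and the other 10 motifs examined in this way did not. NFI, the direct repeat, the E-box near TAATTA, ETS and HNF1 were not examined in this way. For CTCF, also a rare site, the other orders ranged from 0.2 to 2.95, so high ratios of rare motifs lack such a background. The other orders were counted with the main controls only. With repeat-matched controls the EBF ratio was 1.40 (1.23 to 1.59), below 1.48, while the homeodomain and MEF2 ratios were 1.46 and 1.51.

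**Figure D5:**
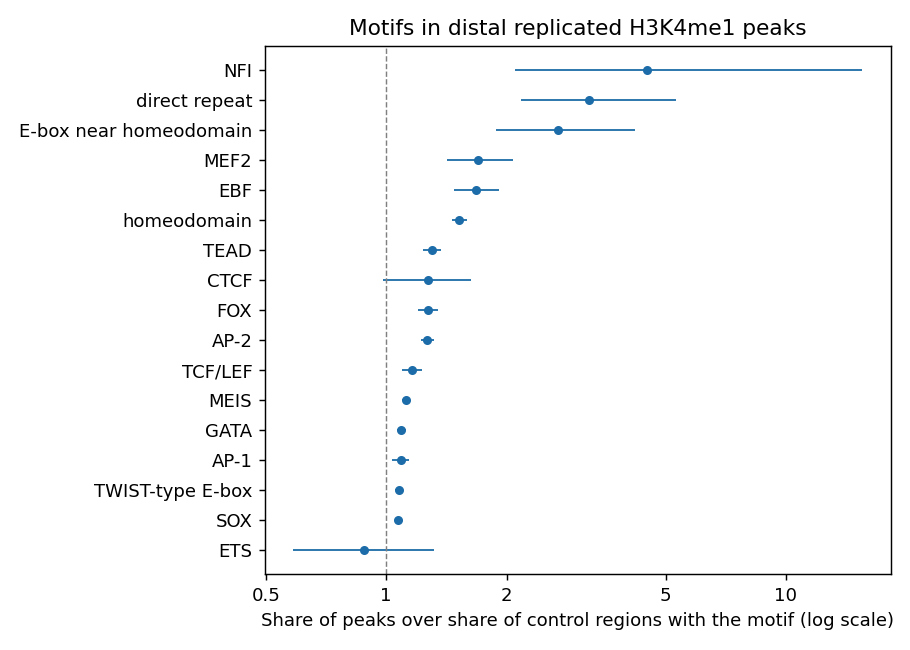
Share of distal replicated peaks with a motif divided by the share of matched control regions (log-scaled horizontal axis), for each motif (vertical axis) except HNF1. Points are ratios and lines 95% bootstrap intervals; the homeodomain site lies at 1.52 and the E-box near it at 2.69.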

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

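The gene list tests with a threshold of -log10 q of 5, peaks overlapping both replicates, random lists matched on density and CpG, and autosomal genes alone, and the motif ratios with repeat-matched controls and 300 tries per control region, were added after seeing the data. Cranial mesenchyme, facial signalling and facial ectoderm passed the test in all 15 settings, with ratios of 2.99 to 6.27, 2.79 to 4.90 and 2.09 to 3.10, each lowest with lists matched on promoter CpG. The olfactory receptors had no ratio with lists matched on promoter CpG. Some lists that had not passed did so elsewhere: cartilage and bone with 1 gene per 200 kb (2.505) and at -log10 q of 5 (2.27), forebrain and eye within 20 kb (2.93) and at -log10 q of 5 (2.48), cranial neurons (2.54) and head mesoderm (3.15) within 20 kb, and housekeeping genes within 100 kb (1.91). Within 50 kb, head mesoderm (main 1.74), forebrain and eye (2.24) and cranial neurons (1.97) were at 1.30, 1.23 and 1.28 matched on promoter CpG in place of density, and at 1.72, 1.78 and 1.67 matched on both. With a replicate left out, cartilage and bone ranged from 1.90 to 2.26 and forebrain and eye from 2.12 to 2.57, each passing in replicate 2's list alone. Ratios not past the threshold crossed 1 as follows: within 20 kb, cardiac 0.97 and spermatid 0.60; within 100 kb, limb and trunk 0.96; by number of peaks, erythroid 1.05 and Hox 1.23; without matching, erythroid 1.08, Hox 1.67 and lymphoid 1.10; matched on promoter CpG, erythroid 2.83, Hox 1.25, limb and trunk 0.99, lymphoid 1.79 and pharyngeal endoderm 0.96; matched on density and CpG, erythroid 1.86 and lymphoid 1.91; with 1 gene per 200 kb, erythroid 1.09. The cause was not tested.

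At -log10 q of 5, replicate 1 kept 106448 peaks, replicate 2 70977 and the pooled list 134825. The share of replicate 1 found in replicate 2 was 63.1% with both at -log10 q of 2, 62.5% of peaks by 1 bp, 51.3% by most of the peak (50% or more) and 68.0% with equal numbers of top peaks; the reverse shares were 81.6%, 80.9%, 72.1% and 77.3%. At -log10 q of 2, 69.0% of pooled peaks were kept, and rho was 0.634 for regions past it in both replicates. Distal peaks were 84.8% beyond 1 kb and 73.8% beyond 5 kb, and 81.5 to 83.7% in single replicates. Around summits, CTCF had a ratio of 1.75, past the threshold, and ETS 1.29. With a replicate left out ETS turned from 0.88 to 1.58 and 1.73, the latter in replicate 2's list with an interval (1.10 to 2.94) above 1, NFI ranged from 1.43 to 13.0 and the E-box near TAATTA from 3.0 to 7.0 (main 2.69), with few sites counted. With repeat-matched controls, AP-1 was at 0.983 and CTCF at 0.981. The E-box near TAATTA was then at 2.0 (1.38 to 2.96) and AP-2 at 1.118 (main 1.27), while FOX was at 1.28 (main 1.27). With 300 tries, run during the analysis and not kept as the main setting, 19323 peaks had a control, and ratios were 2.07 for NFI (main 4.5), 2.37 for the direct repeat (3.22), 1.51 for EBF (1.68) and 1.55 for the homeodomain site (1.52), with no call changed. Ratios of rare motifs thus depend on the controls drawn. No ratio was given for HNF1, which was too rare. Unknown read depth limits every difference in peak number between the replicates.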

Other observations

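The tests on local gene density, promoter CpG classes, gene families, repeat-matched controls and the peaks left at a lower dosage were chosen only after the results were seen. The dip of H3K4me1 at start sites belonged to genes with CpG-rich promoters. Around 10072 such genes, 40.0 ± 0.38% of bases were covered between 500 and 250 bp upstream, 23.5 ± 2.61% in the first 250 bp downstream and 59.6 ± 2.21% between 750 and 1000 bp downstream (SD, n = 2 throughout). Around 8606 genes with CpG-poor promoters the order was turned, with 11.8 ± 0.99% upstream, 17.8 ± 0.80% at the start and 11.4 ± 0.81% downstream, and both replicates showed it.

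Among 11 gene families looked up by symbol, without a test, some lay like the olfactory receptors in sequence with few H3K4me1 peaks. No replicated peak lay within 50 kb of 189 of 206 type 1 vomeronasal receptor genes, 107 of 120 of type 2, 20 of 22 major urinary protein genes, 46 of 64 defensin genes, 22 of 35 bitter taste receptor genes, 17 of 26 killer lectin receptor genes, 36 of 56 clustered protocadherin genes and 22 of 57 keratin-associated protein genes, against 15.9% of all genes. The share was lower for the trace amine receptors, 2 of 15, although their median covered length was only 0.229 kb, and for the Zfp genes, 55 of 394, while all 67 replication histone genes had a peak in that range, with a median of 17.8 kb covered. Several of these families hold similar copies, to which reads cannot always be assigned, so an absence of peaks there is less certain than elsewhere.

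The X chromosome had 8.07 replicated peaks per Mb, and a low density of genes or of sequence outside repeats was tested as the source. Genes on X had 0.033 times the median covered length of autosomal genes at the same local density (0.205 kb against 6.12 kb), and the covered share of bases outside repeats was 0.114 of the autosomal median, which argues against both as the whole cause. A lower signal from 1 active X chromosome per cell was tested on 256 X genes with CpG-rich promoters: matching their share with a peak of fold enrichment 3 or more to the autosomes required a dosage factor of 0.553 ± 0.02 (SD, n = 2), while no autosome was below 0.823 among the 36 autosomal values that could be computed of 38. This factor was computed from the deficit at promoters, so another cause of lower signal on X could give the same value. Reduced dosage stays a hypothesis for part of the deficit. Multiplying autosomal fold enrichments by the factor left 22.7 ± 1.20% of peaks above the fifth percentile of enrichment, whereas X had 12.9 ± 0.36% of the autosomal median of peaks per Mb. How much of X reads can be mapped to uniquely was not computed. It stays open, as do which genes lie on X, copy number in pools of both sexes, and the authors' control correction.

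The excess of homeodomain sites in distal peaks was set against its technical explanations. Sequences made of the same letters in another order reached a ratio of at most 1.172, below the 1.52 of TAATTA, which argues against base composition. With controls also matched on repeat-masked sequence the ratio was 1.46 (95% interval 1.39 to 1.53), which argues against repeats in the controls. The excess may reflect use of these elements by the homeodomain factors of the mesenchyme, which is a hypothesis. The design holds a single tissue, so no biological explanation was tested, and other tissues with homeodomain factors could show the same.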
